A study of Mus musculus with 2 samples.

How the data were processed

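The deposited count matrices were used as they were, with 10014 and 9703 barcodes. Per the file headers the counts were made with cellranger 6.1.2, whereas the submitters' notes list Cell Ranger 5.0.1, Scanpy and the mm10 genome. Whether intronic reads were counted, and whether ambient RNA or doublets were removed before deposit, is not given in the sources used here. Gene positions came from GENCODE vM21 on GRCm38, in which 32158 of 32285 gene identifiers were found.

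Cells with at least 1000 UMIs, at least 500 genes and at most 15% mitochondrial UMIs were kept, 8714 flox and 8435 cKO. Scrublet's automatic threshold called 0 flox and 2 cKO doublets. The fallback planned for that case was used, and the highest scores were removed at 0.8% per 1000 cells, 607 flox (6.97%) and 569 cKO (6.75%). Counts were scaled to 10000 per cell and logged, and 2000 variable genes were chosen by dispersion in bins of mean expression, with mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and Ptges3 left out. Clusters came from 30 principal components, 15 exact nearest neighbours, a shared-neighbour graph and the Leiden method at resolution 1.0 (seed 0). Both libraries were clustered together without integration, and genes that overlap ribosomal RNA sequence were not among those left out. Differences between the libraries can therefore split cells of 1 type into separate clusters. Neuron-like cells were clustered again with 20 components. There were 32 clusters, 8 of them unnamed, and 34 neuron sub-clusters, 8 of them unnamed.

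Clusters were named from 20 marker sets and subtypes from 6. A marker counted when its level, with 10 CPM added, was at least 1 log2 unit above the 25th percentile of the clusters. It also had to be found in 25% of cells, and 3 such markers were needed. The 10 leading genes had to hold a marker of the class or subtype and no more of another. Clusters with markers of unlike classes stayed unnamed, among them clusters 27 (63 flox and 41 cKO cells) and 29 (1 and 48 cells), which held neuron markers. Most choices, including filters, clustering, lists, intervals and the alternatives, were written down before the data were examined. Departures from that design were the 25th percentile in place of the median, a Schwann-like class of clusters 5, 8 and 9 only, proliferating glia kept apart, and clusters 2 and 4 left unnamed. Settings added after seeing the data are named as such.

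UMIs were summed over the cells of a class in each library. Levels have exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95%, and a share of 0 has the upper Clopper-Pearson limit. A gene was measured with at least 50 UMIs over both libraries, and a list member counted as higher or lower at 0.5 log2 or more. The 30 gene lists were compared with 10000 random lists drawn from the 100 genes nearest in mean expression. Cells were called cycling with 3 of 10 markers, after thinning to 1000 UMIs. No statistical test between the libraries was made, because cells and genes are not replicates.

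Genes were named by a fixed rule. For each main class the rule took the 10 genes highest and 10 lowest by the interval bound nearest to no difference, among those with at least 100 UMIs over both libraries. It left out mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes, and genes over 5-fold higher in another class. From each list with at least 5 members measured, the 2 highest and 2 lowest were taken. Ptges3, Ptger1 to Ptger4 and the sodium channels were always taken, and other classes had 3 genes each way. Results of some genes are not reported here.

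Scaling by the class total left the median log2 ratio of all measured genes at -0.12 in satellite-glia-like, -0.10 in fibroblast-like and -0.11 in mural-like cells, against -0.02, -0.02 and 0.01 with TMM factors. In neuron-like cells the mean of each cell's CPM gave -0.11 and thinning -0.12. In simulated data with known differences, the intervals covered the true ratio of 95.55% (neuron-like), 95.9% (Schwann-like) and 96.35% (satellite-glia-like) of all genes, changed ones included. The simulated counts were Poisson draws, so this coverage says nothing about variation between libraries. The size rule found 88.1%, 79.0% and 71.6% of 1.5-fold differences, and 0.43%, 2.74% and 1.56% of unchanged genes passed it.

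Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.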

Results

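Single-cell 3′ RNA libraries were made from dorsal root ganglia, the groups of sensory neuron cell bodies beside the spinal cord, of mice at postnatal day 4. There was 1 library from mice with floxed Ptges3 alleles (the flox library) and 1 from mice that also carried Dhh-Cre (the cKO library), a Cre driven by desert hedgehog sequence that acts in the Schwann cell lineage. Ptges3 encodes p23, a cochaperone of HSP90 that is also described as a cytosolic prostaglandin E synthase. The series concerns prostaglandin E2 made by Schwann cells and the excitability of sensory neurons, so the comparison asks how the cells of the ganglion differ when the glia lose Ptges3. The flox library held 10014 barcodes with 132620886 UMIs (unique molecular identifiers, each counting 1 RNA molecule), and the cKO library 9703 barcodes with 78144437 UMIs. After the cell filter and doublet removal there were 8107 flox and 7866 cKO cells, with medians of 6886 and 4319.5 UMIs per cell. With 1 library per genotype no difference here has a replicate check, and the 95% intervals cover counting error only. Levels (CPM) are the UMIs of a gene scaled by the UMI total of the class, and ratios are log2 of cKO over flox. For a gene list, the interval gives order statistics of its members, which are not replicates, and the percentile is the place of the median among 10000 random lists of similar expression.

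Ptges3 (ENSMUSG00000071072, GRCm38 chromosome 10, 128058954 to 128077272, forward strand) was lower in the cKO library in each of the 4 glial groups and higher in neuron-like, fibroblast-like, macrophage-like, endothelial-like and mural-like cells. In Schwann-like cells it stood at 230.0 CPM (222 to 238) in the flox library and 113 CPM (102 to 125) in the cKO library, a log2 ratio of -1.02 (-1.18 to -0.87). Satellite-glia-like cells, the glia that wrap neuron cell bodies, had 206 and 132 CPM, a ratio of -0.65 (-0.88 to -0.42), which was -0.17 when the cells were divided into finer clusters (Leiden resolution 2.0). Ratios were -1.09 (-1.26 to -0.92) in the unnamed glial clusters 2 and 4 and -1.18 (-1.35 to -1.01) in proliferating glia. Neuron-like cells had 276 CPM (272 to 280) in the flox and 390.4 CPM (385 to 396) in the cKO library, a ratio of 0.50 (0.47 to 0.53). The ratio was 0.32 (0.23 to 0.42) in fibroblast-like, 0.30 (0.01 to 0.58) in macrophage-like, 0.63 (0.38 to 0.88) in endothelial-like and 0.58 (0.28 to 0.87) in mural-like cells. The counts come from the 3′ end of the RNA and the labels do not say which exons are floxed, so a UMI can come from an allele that has lost them.

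**Figure D1:**
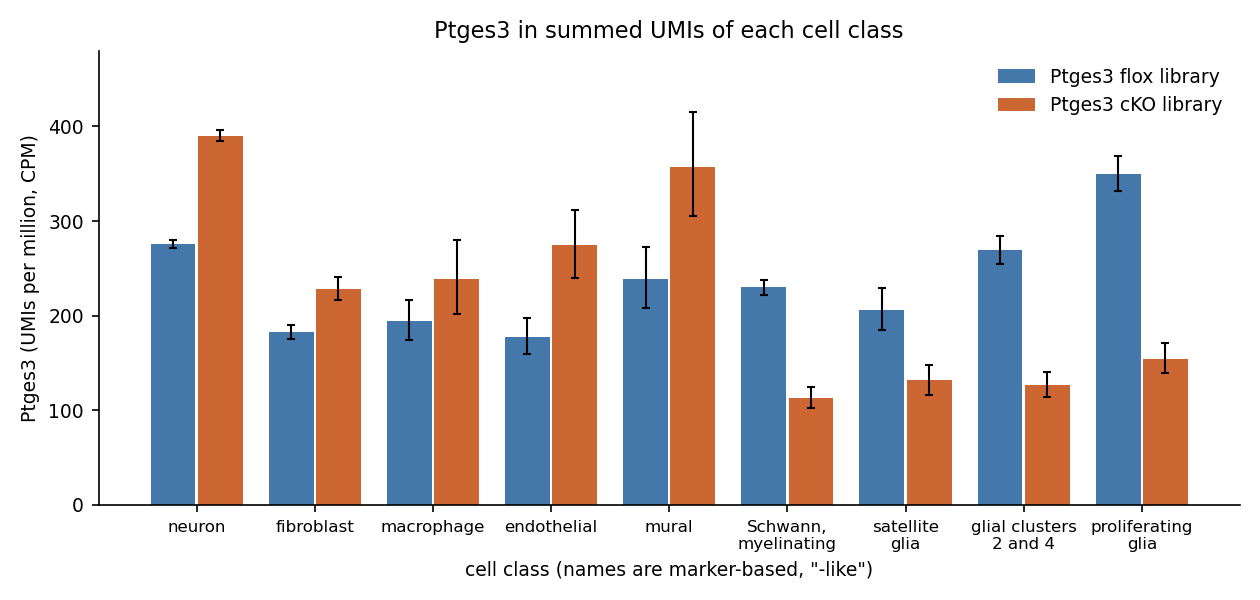
Ptges3 level (CPM, vertical axis) in each cell class of the flox and cKO libraries, with exact 95% Poisson intervals that cover counting error only. Schwann-like cells stand at 230.0 and 113 CPM and neuron-like cells at 276 and 390.4 CPM.

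The cKO library held a larger share of neuron-like cells and a smaller share of Schwann-like cells than the flox library. Neuron-like cells made up 18.7% (17.8 to 19.5) of flox and 38.6% (37.5 to 39.7) of cKO cells, a log2 ratio of 1.05 (0.96 to 1.14). They differed in depth, with medians of 47547 and 9074 UMIs, and 14.7% of flox but 52.3% of cKO neuron-like cells had under 10000 UMIs. Clusters 10 and 12 held 407 and 279 of the 1514 flox neuron-like cells, whereas clusters 0 and 6 held 957 and 823 of the 3038 in the cKO library, and cluster 23 (190 cells) was found in the cKO library only. Leaving out the neuron-like cells under 10000 UMIs and 5 clusters nearly absent from the cKO library, a setting chosen after seeing the data that takes out more neuron-like cells of the cKO library, gave shares of 19.1% and 23.1% and a ratio of 0.27. Schwann-like cells, named from markers of myelinating Schwann cells, made up 22.2% (21.3 to 23.1) of flox and 9.53% (8.89 to 10.2) of cKO cells, a ratio of -1.22 (-1.34 to -1.09), with medians of 7059 and 4144.5 UMIs. Clusters 5 (930 cells) and 8 (826 cells) held most of the flox Schwann-like cells and cluster 9 (702 cells) most of those of the cKO library. When clusters were made without the myelin, cholesterol synthesis and myelinating Schwann marker genes, also chosen after seeing the data, the Schwann-like shares were 22.1% and 9.46%, and at Leiden resolution 2.0 they were 17.1% and 3.81%.

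Satellite-glia-like cells made up 4.56% (4.12 to 5.04) of flox and 8.11% (7.52 to 8.74) of cKO cells, but 4.16% and 4.11% when the myelin-related genes were left out of the clustering. Clusters 2 and 4, which expressed glial lineage genes but met the naming rule of no class, made up 12.5% and 12.7%. The first was nearly confined to the flox library (968 and 42 cells) and the second to the cKO library (46 and 958 cells). Proliferating glia made up 6.11% and 7.65%, and all glial clusters together 45.3% (44.3 to 46.4) and 38.0% (36.9 to 39.1). Fibroblast-like cells were at 15.8% and 14.96%, with cluster 17 (337 and 3 cells) nearly all from the flox library. The shares were 4.26% and 1.95% for macrophage-like, 2.07% and 1.89% for endothelial-like, 1.53% and 2.19% for mural-like and 0.629% and 0.267% for erythroid-like cells. The macrophage-like class included cluster 30, with 42 flox cells and 0 cKO cells. Without the clusters nearly absent from the cKO library, a choice made after seeing the data, the macrophage-like shares were 4.35% and 1.95%. Clusters 15 and 21 (352 and 240 cells), led by the myelin genes of oligodendrocytes, and the astrocyte-like cluster 26 (169 cells) were found in the flox library only, and 0 of 7866 cKO cells allows a share of up to 0.0469%. A cluster mostly of 1 library may reflect that library and not a cell type.

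**Figure D2:**
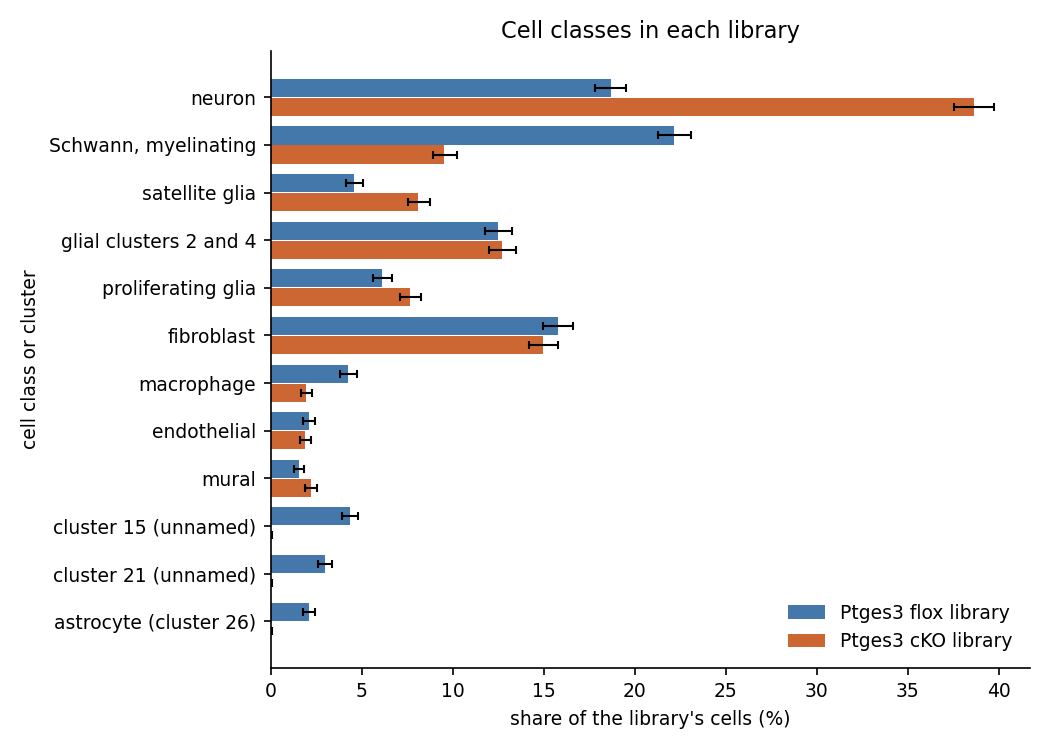
Share of cells (percent of the library, horizontal axis) in each class of the flox and cKO libraries, with exact 95% Clopper-Pearson intervals. Neuron-like cells are at 18.7% and 38.6% and Schwann-like cells at 22.2% and 9.53%.

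Schwann-like cells of the cKO library had lower summed levels of myelin and cholesterol synthesis genes, but not in each of their clusters. Of 25 measured myelin genes, 17 were lower and 1 higher by at least 0.5 log2, with a list median of -0.73 (-0.98 to -0.42) at percentile 0. Egr2 (chromosome 10, 67535475 to 67542188), the transcription factor that drives peripheral myelination, stood at 276 CPM in the flox and 57.9 CPM in the cKO library, a ratio of -2.25 (-2.47 to -2.05). The myelin scaffold gene Mpp6 was higher at 0.56 (0.51 to 0.61), but its ratio over all glia together was -0.01, and Dhh, whose promoter drives the Cre, was at -0.03 (-0.12 to 0.07). Cldn11, a tight junction gene of oligodendrocyte myelin, was the lowest member at -2.27 (-4.18 to -0.86), on 81 and 4 UMIs, and was higher in another class, so free RNA can contribute to it. All 24 cholesterol synthesis genes were measured, and 20 were lower and 0 higher, with a median of -0.88 (-1.10 to -0.69) at percentile 0. Among them were Fdft1, which makes squalene, at 261 and 90.1 CPM (-1.54, -1.71 to -1.37) and the sterol dehydrogenase Nsdhl at 181 and 64.6 CPM (-1.48, -1.69 to -1.29). The libraries fill different clusters of this class. Cells were placed in clusters by their expression, so likeness of the libraries within a cluster can follow from the placing. In cluster 5 the summed myelin genes were higher in the 24 cKO cells than in the 930.0 flox cells (36999 CPM flox, 45402 CPM cKO), and so were the cholesterol synthesis genes (2344 and 2954 CPM). In cluster 8, again with 24 cKO cells, myelin genes were at 180885 and 135966 CPM and cholesterol synthesis genes at 11540.2 and 11591 CPM. In cluster 9, with 41 flox cells, they were at 117333 and 49895 CPM and at 6048 and 3985 CPM. Over all glia together, a grouping chosen after seeing the data, the myelin median was -1.22 (-1.71 to -0.96), and with clusters made without these genes it was -0.74. At Leiden resolution 2.0 the medians were nearer to 0, at -0.31 for myelin and -0.16 for cholesterol synthesis, and at resolution 0.5 the latter was -0.48.

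**Figure D3:**
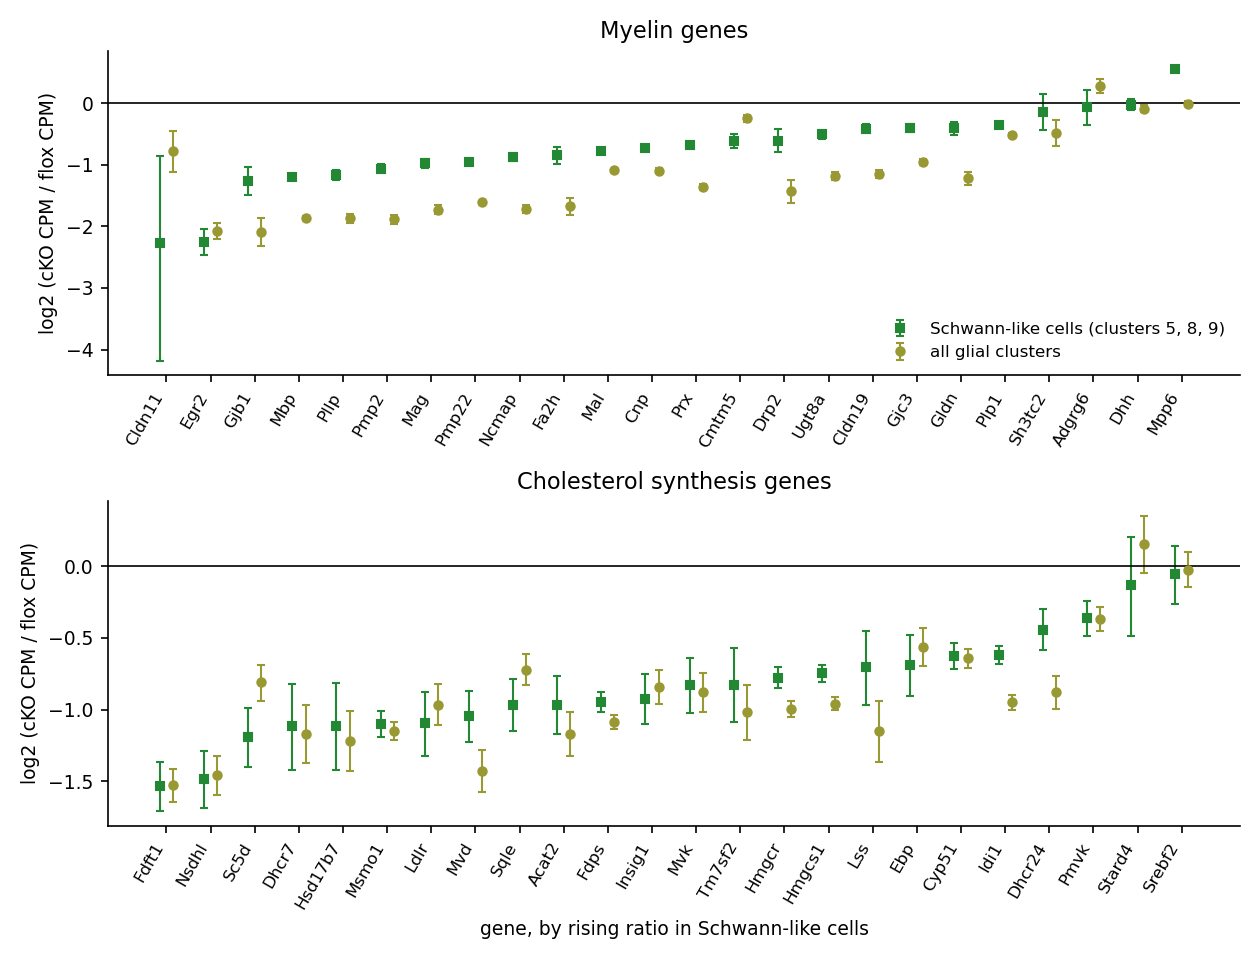
Log2 ratios (cKO over flox) of myelin and cholesterol synthesis genes in Schwann-like cells, with exact 95% intervals for counting error. Egr2 stands at -2.25, Fdft1 at -1.54 and Mpp6 at 0.56.

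Heat shock genes were higher and immediate early and interferon genes lower in cKO Schwann-like cells, while the interval of the inflammation list spanned 0. The heat shock and dissociation stress list had 10 of 16 members higher and 1 lower, with a median of 0.67 (0.07 to 1.77) at percentile 100. Hspa1b, an inducible HSP70, was at 54.7 and 254 CPM (2.22, 2.08 to 2.36), though it shares most of its sequence with Hspa1a (288 and 983 CPM). Hsph1, a nucleotide exchange factor of HSP70, was at 28.9 and 130.1 CPM (2.17, 1.98 to 2.37). The 1 lower member, Socs3, a feedback inhibitor of cytokine signalling, was at 316 and 44.0 CPM (-2.84, -3.09 to -2.61). Of 23 immediate early and activity-regulated genes, 13 were lower and 2 higher, with a median of -0.78 (-1.33 to -0.13). The transcription factor genes Fos (2095 and 566 CPM, -1.89, -1.95 to -1.82) and Junb (601 and 164 CPM, -1.88) were lower, and the growth arrest gene Gadd45b (138 and 462 CPM, 1.75, 1.65 to 1.84) was higher, though another class held more of it and free RNA can contribute. Over all glia together the list's median was -0.23. Interferon response genes had a median of -0.47 (-1.27 to -0.10; 8 of 16 lower, 0 higher), with Isg15, a ubiquitin-like modifier, at 107 and 28.1 CPM. Inflammation genes had a median of -0.79 (-2.67 to 0.43; 6 of 10 lower, 1 higher), with the chemokine gene Cxcl1 at 18.5 and 2.90 CPM and the transcription factor gene Cebpb at 0.88 (0.75 to 1.00), both with higher levels in another class. HSP90 chaperone genes, partners of p23, had a median of 0.29 (0.06 to 0.48; 4 of 18 higher, 0 lower).

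Other lists in Schwann-like cells were less even. The 6 measured prostaglandin synthesis genes had a median of -0.13 (-1.02 to 0.28), and the 2 lower ones were Ptges3 itself and Ptgds, the prostaglandin D synthase, at -0.56 (-0.90 to -0.24), which another class held at a higher level. Immature and repair Schwann cell genes were at 0.22 (-0.39 to 0.75; 4 of 16 higher, 2 lower), and Schwann trophic factors at -0.25 (-1.17 to 0.07; 1 of 14 higher, 6 lower), with Il34, a ligand of the macrophage receptor CSF1R, at 43.6 and 17.4 CPM. Basal lamina and matrix genes were at 0.25 (-0.04 to 0.33; 2 of 19 higher, 2 lower). Hypoxia and glycolysis genes were at -0.38 (-0.58 to 0.15; 2 of 18 higher, 5 lower), with the glycolytic enzyme gene Gapdh at 535 and 312 CPM. Glucocorticoid receptor targets were at -0.27 (-1.71 to 0.41; 2 of 13 higher, 5 lower), and nuclear genes of the mitochondrial respiratory chain at 0.23 (0.08 to 0.40; 6 of 28 higher, 0 lower). Caudal Hox genes, which mark body level, were at -0.99 (-2.02 to -0.16; 4 of 5 lower), and rostral Hox genes at 0.02 (-1.19 to 0.53; 2 of 9 higher, 3 lower). Neurotrophic factor receptors were at 0.57 (0.01 to 1.38; 9 of 13 higher, 1 lower) and sodium channels at 0.63 (-0.43 to 1.67; 5 of 8 higher, 0 lower), with neuronal genes among the highest members, so free RNA of neurons can contribute. The potassium channel list had a median of -0.44 (-0.91 to 0.83; 3 of 9 higher, 4 lower), with Kcna1, a delayed rectifier, at 238 and 422 CPM and Kcnk1, a leak channel, at 117 and 51.0 CPM. The 10 highest genes by the fixed rule included Cxcl14, a chemokine gene (23.2 and 152 CPM), and Tnfrsf12a, the TWEAK receptor gene (54.2 and 184 CPM). The lowest included Dusp6, a phosphatase of ERK (95.4 and 23.2 CPM), and Txnip, an inhibitor of thioredoxin (121 and 30.7 CPM), whose ratio of -1.98 was -0.68 at Leiden resolution 0.5. The free RNA list (glial, blood and matrix genes, some of them genes of Schwann cells) had a median of -0.78 (-1.53 to -0.40; 10 of 15 lower, 1 higher), and 0.01 with each library clustered alone.

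Satellite-glia-like cells of the cKO library also had higher heat shock genes, with a smaller difference in cholesterol synthesis and little in myelin genes. The heat shock list had 10 of 16 members higher and 1 lower, with a median of 0.71 (0.05 to 1.61) at percentile 100. Hspa1b was at 75.3 and 298 CPM (1.99, 1.71 to 2.27), Hsph1 at 22.9 and 110.3 CPM (2.27, 1.77 to 2.80) and Hsp90aa1, the stress-inducible HSP90, at 606 and 1168 CPM (0.95, 0.84 to 1.05). Cholesterol synthesis genes had a median of -0.35 (-0.76 to -0.13; 11 of 24 lower, 0 higher), with Dhcr7, which makes cholesterol from its last precursor, at 89.4 and 32.1 CPM (-1.48, -1.92 to -1.05). The median was -0.17 with clusters made without these genes. Myelin genes were at -0.19 (-0.59 to 0.01; 6 of 19 lower, 0 higher) and HSP90 chaperone genes at 0.17 (-0.06 to 0.61; 5 of 17 higher, 0 lower). Immediate early genes were at 0.15 (-0.35 to 0.91; 7 of 22 higher, 4 lower), with Fos at 6292 and 2694 CPM (-1.22, -1.27 to -1.18). Hes1, a Notch target, was at 83.5 and 252 CPM (1.59, 1.32 to 1.87), and Rel, an NF-kappa-B subunit gene, at 18.2 and 103.5 CPM (2.51, 1.96 to 3.10). Socs3 was at 937 and 262 CPM (-1.84, -1.98 to -1.69), and Kcna2, a delayed rectifier potassium channel gene, at 121 and 58.3 CPM (-1.05, -1.39 to -0.72). All measured genes of this class had a median of -0.12, or -0.02 with TMM factors, so its ratios lie slightly below those of the other main classes.

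**Figure D4:**
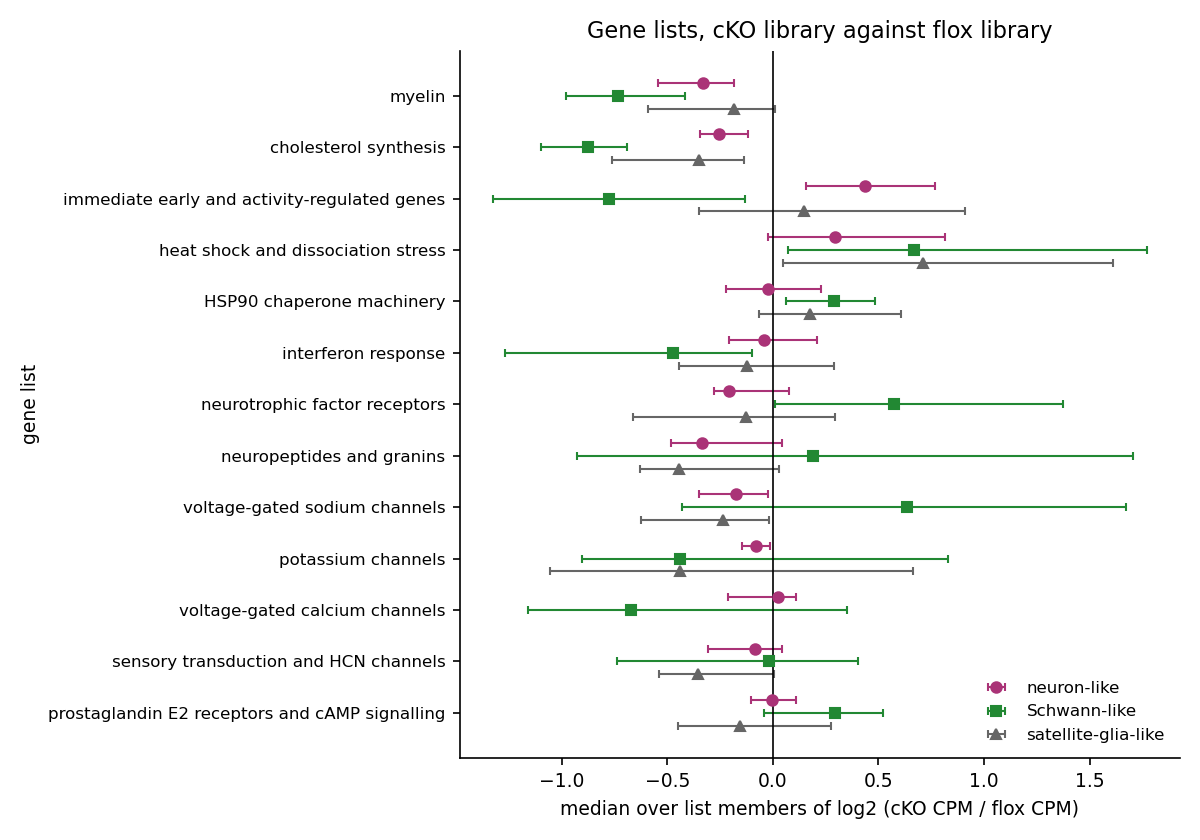
Median log2 ratio (cKO over flox) of each gene list in neuron-like, Schwann-like and satellite-glia-like cells, with order-statistic intervals over the members. In Schwann-like cells myelin stands at -0.73 and heat shock at 0.67, and in neuron-like cells sodium channels stand at -0.18.

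In neuron-like cells, the list of sodium channel subunit genes and FGF genes that bind the channels was slightly lower in the cKO library, and prostaglandin E2 receptor and cAMP genes stood near equal. None of the 16 measured members of that list differed by 0.5 log2 or more, and their median was -0.18 (-0.35 to -0.02) at percentile 2.02. Scn9a (chromosome 2, 66480080 to 66634962), which encodes Nav1.7, a channel that amplifies small depolarisations in nociceptors, was at 468 and 367 CPM (-0.35, -0.38 to -0.33). Scn10a (chromosome 9, 119608456 to 119719322), for the tetrodotoxin-resistant channel Nav1.8, was at 359 and 308 CPM (-0.22, -0.25 to -0.19), and its neighbour Scn11a, for Nav1.9, at 276 and 225 CPM (-0.29, -0.32 to -0.26). The median was -0.50 when each cell counted equally and -0.61 after thinning to 1000 UMIs, with 13 genes measured, and -0.13 (-0.27 to 0.03, percentile 6.64) in neuron-like cells of at least 10000 UMIs, a limit chosen after seeing the data. Counting each cell equally and thinning both give shallow cells more weight than the sums do. The 26 measured prostaglandin E2 receptor and cAMP signalling genes had a median of 0.00 (-0.10 to 0.11) at percentile 67.3, with 1 higher and 0 lower by 0.5. Among the receptors, Ptger1 was at 6.02 and 5.10 CPM (-0.24, -0.47 to -0.01), though 0.17 after thinning, Ptger3 at 16.3 and 15.2 CPM (-0.10, -0.24 to 0.03) and Ptger4 at 4.63 and 4.80 CPM (0.05, -0.19 to 0.30). Ptger2, the 1 higher member, was at 1.45 and 2.71 CPM (0.90, 0.52 to 1.29) and was higher in another class, so free RNA can contribute. Crtc1, a CREB coactivator, was at 14.5 and 20.0 CPM (0.46, 0.33 to 0.59).

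**Figure D5:**
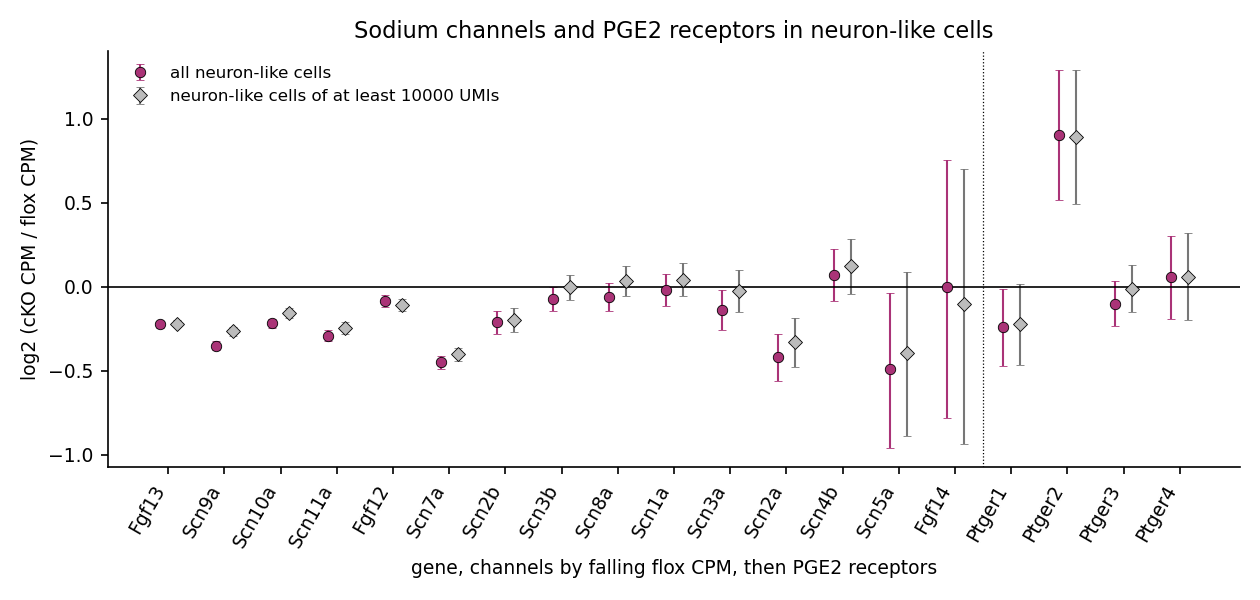
Log2 ratios (cKO over flox) of voltage-gated sodium channel and prostaglandin E2 receptor genes in neuron-like cells, with exact 95% intervals for counting error. Scn9a stands at -0.35, Scn10a at -0.22 and Scn11a at -0.29.

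The other channel lists of neuron-like cells had medians near 0. Potassium channels were at -0.08 (-0.15 to -0.01; 1 of 45 higher, 4 lower), with Kcnk18, the leak channel TRESK, at 97.6 and 56.0 CPM (-0.80, -0.87 to -0.74) and Kcnh5, an ether-a-go-go channel, at 1.73 and 3.03 CPM (0.81, 0.45 to 1.16). Calcium channels were at 0.02 (-0.21 to 0.11; 0 of 17 higher, 1 lower). Sensory transduction and HCN channels were at -0.08 (-0.31 to 0.05; 2 of 28 higher, 3 lower), with the ATP receptor gene P2rx2 at 4.24 and 2.60 CPM (-0.71, -1.02 to -0.41). The cold receptor gene Trpm8 was at 3.67 and 5.59 CPM (0.61, 0.36 to 0.86), but at -1.07 when standardised to the mean subtype shares. Synaptic vesicle genes were at -0.03 (-0.24 to 0.08; 0 of 30 higher, 2 lower). Sensory neuron transcription factors were at -0.05 (-0.18 to 0.20; 2 of 24 higher, 0 lower), with Mafa, a factor of mechanoreceptors, at 4.61 and 8.69 CPM. Neurofilament and axon cytoskeleton genes were at -0.12 (-0.22 to 0.00; 0 of 25 higher or lower), with Nefm at 850.5 and 1161 CPM and Tubb3, a neuronal tubulin, at 2393 and 1730.3 CPM.

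Some neuropeptide genes were lower and some immediate early genes higher in cKO neuron-like cells. Neuropeptides and granins had a median of -0.34 (-0.48 to 0.05; 0 of 21 higher, 5 lower) at percentile 0.01. Calca (chromosome 7, 114631478 to 114636357), which encodes calcitonin gene-related peptide, was at 1989 and 1231 CPM (-0.69, -0.71 to -0.68), and the granin gene Scg2 at 184 and 127 CPM (-0.53, -0.58 to -0.49). Neurotrophic factor receptors were at -0.21 (-0.28 to 0.08; 0 of 15 higher, 1 lower), with Gfra3, the artemin receptor, at 92.9 and 60.9 CPM (-0.61, -0.67 to -0.55). Immediate early and activity-regulated genes had a median of 0.44 (0.16 to 0.77; 13 of 28 higher, 1 lower) at percentile 100, led by Fosl2 (4.14 and 11.2 CPM) and Gadd45b (24.7 and 61.1 CPM). Heat shock genes were at 0.29 (-0.02 to 0.82; 6 of 16 higher, 0 lower), led by Hspa1a (16.4 and 131 CPM), and axon injury genes at 0.19 (-0.05 to 0.49; 3 of 15 higher, 0 lower), with the injury-induced factor Atf3 at 41.8 and 73.7 CPM. All 4 of these leading genes were higher in another class, so free RNA can contribute to them. Glucocorticoid receptor targets were at 0.30 (-0.01 to 0.77; 4 of 13 higher, 0 lower) and prostaglandin synthesis genes at 0.54 (-0.03 to 0.99; 6 of 9 higher, 0 lower). In cells of at least 10000 UMIs, 3 of 9 prostaglandin synthesis genes were higher and 0 lower, with a median of 0.46 (0.02 to 0.84). Of the higher ones, Hpgds had 41 flox and 51 cKO UMIs there and Ptgis 28 and 33, so they rest on few counts. Ptges2, with more counts, was at 51.1 and 46.1 CPM (-0.15, -0.23 to -0.07). Over all neuron-like cells, Ptges3 itself, at 0.50, is among the 6 higher members. HSP90 chaperone genes were at -0.02 (-0.22 to 0.23; 2 of 19 higher, 0 lower), respiratory chain genes at 0.11 (0.01 to 0.23; 2 of 28 higher, 0 lower), cholesterol synthesis genes at -0.26 (-0.35 to -0.12; 0 of 24 higher, 2 lower) and hypoxia and glycolysis genes at -0.15 (-0.35 to 0.04; 2 of 22 higher, 2 lower). Gapdh was at 1646 and 929.6 CPM (-0.82, -0.84 to -0.81).

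By the fixed rule, the lowest genes of neuron-like cells also included Tmem45b at 169 and 80.6 CPM (-1.07, -1.12 to -1.02), Ndn, the imprinted gene of necdin, at 662 and 362 CPM (-0.87, -0.90 to -0.85), and Sqstm1, the autophagy receptor p62, at 281 and 168 CPM (-0.75, -0.78 to -0.71). The highest included Uts2b, a urotensin-related peptide gene, at 2.19 and 10.3 CPM (2.23, 1.97 to 2.51), Abhd2, a lipid hydrolase gene, at 18.9 and 42.3 CPM (1.17, 1.07 to 1.27), and the exchanger gene Slc24a5 at 39.0 and 81.1 CPM (1.06, 0.99 to 1.13). Genes of other cell types also differed in these cells. Basal lamina genes were at 0.56 (0.15 to 0.70; 11 of 20 higher, 0 lower), cell cycle genes at 0.61 (0.15 to 0.96; 14 of 22 higher, 0 lower), inflammation genes at 0.57 (-0.42 to 0.72; 10 of 16 higher, 3 lower) and the free RNA list at 0.51 (-0.43 to 1.11; 8 of 15 higher, 3 lower). In neuron-like cells of at least 10000 UMIs the cell cycle median was 0.36 and that of the free RNA list 0.17. The free RNA list was at 1.73 in the unnamed sub-clusters, but at -0.42 in C-low-threshold-like, -1.06 in large-diameter-like, 0.12 in non-peptidergic-like and -0.57 in peptidergic-like cells. In the free RNA list, Apoe, a lipid carrier of satellite glia, was at 344 and 927 CPM and the collagen gene Col1a1 at 29.4 and 115 CPM, whereas Mbp, a myelin gene, was at 163 and 90.1 CPM. The myelin list was at -0.33 (-0.54 to -0.18; 2 of 25 higher, 9 lower), but at 0.36 after thinning and at 0.20 without the neuron-like cells with the most glial marker counts. Immature and repair Schwann cell genes were at 0.09 (-0.10 to 0.49; 4 of 19 higher, 3 lower), Schwann trophic factors at 0.23 (-0.10 to 0.44; 4 of 22 higher, 0 lower) and interferon response genes at -0.04 (-0.20 to 0.21; 1 of 20 higher, 2 lower). Rostral Hox genes were at 0.06 (-0.24 to 0.38; 2 of 14 higher, 1 lower) and caudal Hox genes at 0.04 (-0.10 to 0.46; 1 of 10 higher, 0 lower). Sex-linked genes were at -0.22 (-0.58 to -0.20; 0 of 4 higher, 1 lower).

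Among neuron subtypes, named from a fixed set of markers after clustering the neuron-like cells alone, non-peptidergic-nociceptor-like cells made up 45.0% (42.5 to 47.6) of flox and 33.4% (31.7 to 35.1) of cKO neuron-like cells. Peptidergic-nociceptor-like cells made up 18.5% (16.6 to 20.5) and 27.1% (25.5 to 28.7), large-diameter-myelinated-like cells 10.7% and 11.3%, C-low-threshold-mechanoreceptor-like cells 12.0% and 3.46%, and somatostatin-pruriceptor-like cells 3.10% and 0.757%. Unnamed sub-clusters held 10.6% (9.13 to 12.3) and 24.0% (22.5 to 25.6), with median depths of 9990.0 and 5966 UMIs. Among neuron-like cells of at least 10000 UMIs the C-low-threshold-mechanoreceptor-like shares were 14.0% and 6.55% and the unnamed shares 6.20% and 15.8%. When each cell was scored for the markers alone, somatostatin-pruriceptor-like shares were 7.66% and 11.2%, the other way round. The sodium channel list had a median of -0.27 (-0.44 to -0.01; 2 of 14 lower) in peptidergic-like, -0.10 (-0.23 to 0.16; 0 of 14 lower) in non-peptidergic-like, -0.08 (-0.44 to 0.09; 1 of 15 lower) in large-diameter-like and -0.13 (-0.25 to 0.07; 0 of 13 lower) in C-low-threshold-like cells. In the unnamed sub-clusters it was -1.07 (-1.55 to -0.29; 11 of 14 lower), where sub-cluster 13 held 103 of the 161 flox cells and sub-clusters 9 and 12 held 165 and 143 of the 730.0 cKO cells. Other neuronal lists were lower there too, with medians of -1.003 (-1.23 to -0.35; 24 of 38 lower) for potassium, -1.25 for calcium and -1.07 for sensory transduction channels, -0.93 for neurotrophic factor receptors and -0.70 for neuropeptides, so this is not particular to sodium channels. In unnamed flox cells Scn9a (885 CPM) and Scn7a (537 CPM) lay above the named flox subtypes with medians here (430 to 564 and 135 to 481 CPM). Scn10a (380 CPM) lay within them (62.7 to 503 CPM). In unnamed cKO cells Scn9a (275 CPM) lay below the named cKO subtypes (321 to 487 CPM), and Scn7a (189 CPM) within them (107 to 355 CPM). Low ratios in unnamed cells can thus come from the flox side too. The largest non-peptidergic-like sub-cluster was 1 in the flox library (321 of 682 cells) and 0 in the cKO library (376 of 1014), and the largest peptidergic-like sub-cluster was 4 in both (140.0 of 280.0 and 177 of 823).

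Cycling glia were nearly equal in number in the libraries, 351 of 8107 flox and 354 of 7866 cKO cells with at least 3 of 10 proliferation markers after thinning to 1000 UMIs. Of glia alone they made up 9.55% (8.62 to 10.5) and 11.8% (10.7 to 13.1), with fewer glia in the cKO library, and unthinned 588 of 3676 and 580.0 of 2990 did, at median depths of 5794 and 3062 UMIs. In neuron-like cells, which do not divide, 0.264% and 0.296% did so after thinning, and 13.3% and 13.6% unthinned, at 47547 and 9074 UMIs. In Schwann-like cells the thinned shares were 0% and 0.267% and in satellite-glia-like cells 0% and 0.470%. Low shares there are largely built in, because proliferating glia were named from these same markers and kept apart. No cell was too shallow to be thinned. Within proliferating glia the thinned share was lower in the cKO library, 69.9% and 57.6%, and in clusters 2 and 4 it was 5 of 1014 cells (0.160% to 1.15%) and 2 of 1000 (0.0242% to 0.721%). Unthinned, the latter were 7.59% and 1.60%, at median depths of 4006 and 2412.5 UMIs. The cell cycle list had a median of -0.02 (-0.44 to 0.31; 2 of 13 higher, 2 lower) in Schwann-like cells, -0.79 (-1.28 to -0.34; 1 of 19 higher, 13 lower) in clusters 2 and 4 and -0.29 (-0.52 to -0.02; 0 of 22 higher, 7 lower) in proliferating glia.

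In the other classes the genes with the highest ratios included some that overlap ribosomal RNA sequence, with AY036118 78.8-fold higher in macrophage-like cells and 118-fold higher in mural-like cells of the cKO library. The heat shock list had a median of 1.10 (0.29 to 1.77; 11 of 16 higher, 1 lower) in mural-like, 0.67 (0.14 to 1.42; 10 of 16 higher, 2 lower) in endothelial-like and 0.14 (-0.72 to 0.57; 5 of 16 higher, 4 lower) in macrophage-like cells. Macrophage-like cells had the chemokine genes Ccl2 at 3120 and 456 CPM (-2.77, -2.95 to -2.60) and Ccl7 at 1381 and 143 CPM (-3.27, -3.59 to -2.97), while Hsph1 was at 35.1 and 147 CPM (2.07, 1.59 to 2.56). This class included cluster 30 (42 flox cells and 0 cKO cells), and its values without that cluster are not given here. Mural-like cells had Hspa1b at 32.1 and 436 CPM (3.76, 3.20 to 4.38) and Bst2, an interferon-induced antiviral gene, at 1803 and 245 CPM (-2.88, -3.16 to -2.61). Endothelial-like cells had Hsph1 at 36.3 and 170.2 CPM (2.23, 1.81 to 2.66). Their 3 lowest genes were the transporter genes Slc38a5 at 338 and 1 UMIs (-7.17, -12.48 to -4.68) and Slco1c1 at 262 and 3 UMIs (-5.22, -7.50 to -3.65), and Pglyrp1, a peptidoglycan recognition gene, at 386 and 15 UMIs (-3.45, -4.31 to -2.71). Spinal-cord-type cells were found in the flox library alone (761 flox and 0 cKO cells). The endothelial-like cells of the libraries may therefore differ in tissue of origin, which was not tested. Fibroblast-like cells had Tnfrsf12a at 55.9 and 196 CPM (1.81, 1.67 to 1.95). Their lowest genes were the Wnt regulator Notum at 928 and 3 UMIs (-7.40, -9.68 to -5.85), Wnt4 at 321 and 7.05 CPM and Tff3 at 341 and 0 UMIs, at least 62.2-fold lower against a floor of 3 counts. Without cluster 17, a choice made after seeing the data, Notum had 6 and 3 UMIs and Wnt4 stood at 13.3 and 5.98 CPM.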

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

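Of the tests below, the nuclear RNA test and the test by thinning were written down before their own results were seen. The tests with cells left out, over all glia, of cholesterol synthesis against other classes, and of heat shock genes outside the glia were chosen after the result was seen.

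The larger share of neuron-like cells in the cKO library might come from barcodes holding pieces of neurons or free neuronal RNA. Nuclear RNAs would then lie well below their level in deeper cells. In the cKO library their CPM under 10000 UMIs was 0.718 times (0.712 to 0.724) that at or over 10000, a smaller drop than was predicted, while the ratio in the flox library was 3.76. Among shallow neuron-like barcodes, however, nuclear RNAs stood at 9088 CPM in the cKO and 38314 CPM in the flox library. Of the 223 shallow flox barcodes, 99 were in cluster 22, led by Snhg11, itself among the nuclear RNAs scored. The flox level may therefore not be that of whole shallow cells, and the comparison between libraries cannot decide this. Pieces of neurons or free RNA are not excluded. Spinal-cord-type cells of the flox library together with shallow neuron-like cells are another explanation, and leaving out the one-sided clusters alone gave a log2 ratio of the shares of 0.83, in place of 1.05. Leaving out the shallow cells as well gave 0.27, but 52.3% of cKO and 14.7% of flox neuron-like cells were shallow, so the ratio had to be lower. Shallow cells as the source and a larger share of neurons in the tissue therefore cannot be told apart.

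Lower myelin genes in cKO Schwann-like cells could come from myelinating cells placed in other glial clusters, but over all glia the median was -1.22, which argues against it. Depth could also matter, and after thinning to 1000 UMIs the median was -0.68 (-0.90 to -0.37). Thinning at random leaves the expected fraction of each gene in a cell unchanged, so it mainly gives each cell equal weight. The mean of each cell's CPM, without thinning, also gave -0.68, so thinning cannot show whether depth or cell quality matters. Fewer strongly myelinating cells and lower levels in each cell both stay open. For cholesterol synthesis, the ratios of another class were subtracted from the Schwann-like ratios. Over 24 genes the medians were -0.51 (-0.70 to -0.33) for fibroblast-like and -0.57 (-0.76 to -0.45) for neuron-like cells. For macrophage-like, endothelial-like and mural-like cells they were 0.04, 0.26 and -0.34, with 10, 11 and 7 genes measured. The libraries fill different Schwann-like clusters, so all of these medians can carry the make-up of the class. With finer clusters the Schwann-like median was -0.16, against -0.26 in neuron-like cells in the main setting. Summed levels were lower in the cKO library in cluster 9 (6048 and 3985 CPM). They were not lower in cluster 5 (2344 and 2954 CPM) or cluster 8 (11540 and 11591 CPM), each with 24 cKO cells. Cells were placed in clusters by their expression, so likeness within a cluster can follow from the placing and cannot decide this. A difference shared with other classes and one particular to Schwann-like cells therefore cannot be told apart.

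Higher heat shock genes in cKO glia might reflect handling of the tissue or library quality. The lowest median among 5 classes outside the glial lineage was 0.14 (-0.72 to 0.57), in macrophage-like cells, and the interval in neuron-like cells (-0.02 to 0.82) also spans 0, so a difference in every class and one in some classes cannot be told apart. A response confined to the lineage of Dhh-Cre is argued against by 3 of these 5 classes with intervals above 0: fibroblast-like (0.24 to 0.59), endothelial-like (0.14 to 1.42) and mural-like (0.29 to 1.77). Genes that overlap ribosomal RNA sequence were also higher in the cKO library, at 3.37 in neuron-like, 3.58 in Schwann-like and 3.19 in satellite-glia-like cells. Whether they and the heat shock genes share a cause was not tested.

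Other values stood out. Clusters 15, 21 and 26, of a type found in the spinal cord and not analysed further, held 9.39% (8.76 to 10.0) of flox cells and 0 of 7866 cKO cells. Ptges3 had opposite signs in neuron-like and Schwann-like cells, with log2 ratios 1.52 apart. Immediate early genes did too, with medians 1.22 apart. Neither of these differences was tested.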

How the results depend on the processing

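No paired analysis was possible because the libraries have no shared animal or batch in the labels, and leaving out a replicate was not possible with 1 library per genotype. A value kept its size when it lay within the interval of the main result, which is wide for genes with few counts. For genes, 2001 of 2439 values kept their size, 426 moved and 12 reversed. The settings with a minimum of 10 or 300 UMIs leave a gene's ratio as it is, so their values were kept by construction. For list medians the counts were 1161, 52 and 3 of 1216, and for shares 95, 36 and 2 of 133. The interval of a list median comes from the spread of its members and is often wide, so a kept median says little. The cause of the movements was not tested. The settings over all glia, with genes or clusters left out, or limited to 10000 UMIs were chosen after seeing the data. The Ptges3 log2 ratio of neuron-like cells (0.50) was 0.53 with DESeq2 size factors, 0.60 with the mean of each cell's CPM, 0.55 thinned to 1000 UMIs, 0.54 standardised to the mean subtype shares, 0.47 without the cells with the most glial marker counts and 0.47 (0.469) at 10000 UMIs or more. In satellite-glia-like cells it was -0.17 at Leiden resolution 2.0. In neuron-like cells, thinning gave 0.70 for Adamts19, 0.17 for Ptger1, 0.01 (0.0115) for Fgf12 and 0.48 for Cck. The mean of each cell's CPM gave 0.09 (0.0936) for Fgf12 and 0.01 (0.0114) for Cck, and standardising gave 0.06 (0.0622) for Fgf12 and -1.07 for Trpm8. Cck was 1.61 with no cell filter and 1.67 without the cells with the most glial marker counts. The sodium channel median was -0.50 with the mean of each cell's CPM and -0.61 thinned, and the myelin median 0.36 thinned and 0.20 without the cells richest in glial markers. In Schwann-like cells, Scn3b was 0.19 at resolution 2.0 and Mpp6 -0.01 (-0.0069) over all glia. Their myelin median was -0.31 at resolution 2.0 and -1.22 over all glia, and that of the free RNA list 0.01 (0.0082) with each library clustered alone. The neuron-like share ratio was 0.85 with each library clustered alone, 0.83 without the clusters nearly absent from the cKO library and 0.27 when shallow neuron-like cells were also left out. The Schwann-like share ratio was -1.37 with no filter, -1.66 with the stricter filter, -1.58 and -2.17 at resolutions 0.5 and 2.0, -1.39 with each library alone and -1.44 (-1.4352) without the clusters nearly absent from the cKO library. The satellite-glia-like share ratio was -0.02 (-0.0177) with the myelin and cholesterol genes left out of the clustering. The non-peptidergic-like share ratio was -0.66 (-0.6552) at resolution 2.0 and -0.80 scored per cell. The peptidergic-like one was 1.05 with the stricter filter, 0.86 at resolution 0.5, 0.90 with each library alone and 0.96 with the myelin genes left out. The somatostatin-pruriceptor-like one was 0.54 scored per cell.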

Other observations

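Interferon response genes were lower in the cKO library in fibroblast-like and macrophage-like cells, but not in neuron-like cells (-0.04; 1 of 20 higher, 2 lower). The median was -1.21 in fibroblast-like cells (14 of 19 lower, 0 higher) and -1.23 in macrophage-like cells (10 of 16 lower, 0 higher). The 42 macrophage-like cells of cluster 30 were all from the flox library, and the median without them is not given here. Caudal Hox genes had a median of -1.05 (-3.62 to -0.18) in fibroblast-like cells (7 of 10 lower, 0 higher) but 0.04 in neuron-like cells. The libraries fill the fibroblast-like class from different clusters, and without cluster 17, a choice made after seeing the data, its medians were -0.64 (-1.12 to -0.22; 10 of 16 lower, 0 higher) for interferon response and -0.46 (-1.02 to 0.11; 4 of 9 lower, 0 higher) for caudal Hox genes, with rostral Hox genes at -0.44 (-0.53 to -0.15; 3 of 14 lower, 0 higher). Endothelial-like cells had lower cell cycle genes, with a median of -1.21 (15 of 21 lower, 2 higher).

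Genes that overlap ribosomal RNA sequence (Gm42418, AY036118 and Lars2 together) were higher in the cKO library in each main class. They stood at 606 and 6281 CPM in neuron-like cells (3.37), 1889.7 and 22574 CPM in Schwann-like cells (3.58) and 2124 and 19444 CPM in satellite-glia-like cells (3.19). Spinal-cord-type cells of the flox library expressed the oligodendrocyte genes Mobp (2877 CPM) and Mog (825 CPM) and the astrocyte gene Gfap (1058 CPM).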
